A study of Danio rerio with 18 samples.

How the data were processed

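RNA was measured in caudal fin clips of zebrafish lacking the silencer s1 and of WT siblings at the day of amputation and after 1 and 4 days, in 3 pools of 10 fish per group. Per the labels' protocols, cDNA was made from total RNA, fragmented and tagged with Tn5 transposase, and read as paired ends on a DNBSEQ instrument. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7 and cutadapt 3.5 and aligned with STAR 2.7.10 to danRer11. The deposited table holds 1 signal per gene and library, a read count divided by a size factor of the library, and its name says that the authors counted reads over genes and normalised them. The strand setting of the counting and the gene annotation used are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The fins pooled for each library were from separate fish, per the labels, so replicates are biological.

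The table has 32520 gene IDs and 18 libraries, and 5662 IDs are at 0 throughout. Every library's signals were whole multiples of 1 step, and 100% of values came out as whole reads within a tolerance of 0.001. The factors recovered in this way (0.401 to 2.56) equal the median-of-ratios size factors computed anew from the whole reads. Symbols came from a table of gene names that matched 29201 IDs, 6314 of which share a symbol with another ID; such genes are called copies, and values of near-identical copies are uncertain, since reads can fall on either. Many symbols are those of the human gene. Gene order came from the RefSeq annotation of assembly GRCz12tu, which is not the build of the table, so it was used for which genes neighbour each other and for nothing else; 17008 IDs could be placed and 14379 of them were tested.

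Genes with a signal of at least 10 in at least 3 libraries were tested (22779 genes). Values were log2(signal + 1), so fold changes are on that scale and understate the change of low genes. limma 3.58.1 (R 4.3.3) was fitted with its trend option to the means of the 6 groups, with all 18 libraries giving 1 estimate of the spread on 12 residual degrees of freedom. Two-sided tests were adjusted by the Benjamini-Hochberg method over all tested genes at 0.05, and a gene past that threshold is called. Comparisons were KO against WT at each time and averaged over the times, 1 against 0 dpa and 4 against 0 dpa within each genotype, and the interactions of genotype with these changes. The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

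Whole reads were also tested with edgeR 4.0.16 and DESeq2 1.42.0 as alternatives. The edgeR quasi-likelihood test called 31, 1 and 4 genes between genotypes at 0, 1 and 4 dpa and DESeq2 96, 20 and 15. Genes at 0 in a whole group were given a bound from a floor of 3 reads per library in place of a fitted fold; floors cover counting error only, as reads from PCR are not independent molecules.

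The 34 fixed lists covered AP-1 and immediate early genes, wound and blastema signalling factors, matrix remodelling enzymes, wound and blastema matrix, bone, osteoclasts, fin ray joint and actinotrichia, epidermal layers, mucous cells and ionocytes, macrophages, neutrophils, lymphocytes, inflammatory cytokines, the interferon response, antigen presentation, the cell cycle, pigment cells, endothelium, nerve, erythrocytes, muscle, fibroblasts, the FGF, Wnt, hedgehog and BMP, retinoic acid and Notch pathways, heat shock, the circadian clock, sterol and lipid metabolism, oestrogen-responsive and sex-biased genes and mitochondrially encoded genes. Of 790 entries, 561 matched by symbol, 167 by a shared family symbol and 8 by a synonym, and 54 did not match. Lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation. Neighbouring calls were counted in windows of 20 tested genes against 10000 permutations of gene positions.

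Genes named between genotypes were, at each time, up to 10 higher and 10 lower called genes with the largest changes whose groups did not overlap, with a mean of at least 20 and a descriptive symbol. Added to these were genes called at all 3 times or for the average, up to 4 called members of each list with the largest changes, and the called genes of the fullest window. Genes named over time followed the first and the list parts of this rule. Where fewer than 5 genes were called, all were eligible.

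The fitting, list and window steps were tested on simulated data made from the real means, dispersions and size factors, with 200 changed genes per comparison. At 0 dpa between genotypes, 22% of 2-fold, 68% of 4-fold and 90.0% of 8-fold changes were recovered among 22779 genes, with 4 false calls. At 1 dpa these were 8%, 72% and 92%, with 0 false calls, and at 4 dpa 10.0%, 82% and 86%, with 11 false calls. For the average they were 56%, 92% and 98%, with 11 false calls. A planted list ranked 1 and a planted window of 4 genes was recovered, with a permutation p of 1e-04, the smallest the permutations can give. Simulated genes varied independently of each other, so no libraries differed in many genes at once, as some real libraries did. False calls from such shared differences are not covered by these rates.

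Alternatives were pseudocounts of 0.25 and 8, no filter or a minimum of 50, TMM scaling, median-centred values, both count tests, a replicate block, fits to the compared groups alone, each library left out in turn, other windows and an estimated correlation for lists. A term for low-share libraries, and fits without these libraries, were added after seeing the data. No correction for GC content or gene length was made, as no annotation of the build was used here.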

Results

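Bulk RNA sequencing was carried out on caudal fin tissue of zebrafish that lacked s1, a regeneration-associated silencer, and of their wild-type (WT) siblings. A silencer is a non-coding stretch of DNA that lowers the transcription of genes. The zebrafish caudal fin regrows after amputation, by wound closure, formation of a mass of proliferating cells called the blastema, and outgrowth of new fin rays. Fin clips were taken at amputation (0 days post amputation, dpa), at 1 dpa and at 4 dpa. Each of the 6 groups of genotype and time held 3 libraries, and each library came from a separate pool of 10 fish, which gave 18 libraries in all. Between 58.6 M and 155 M reads per library were assigned to genes (M, 1e6).

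A small set of genes took very unequal shares of these reads. The 5 most abundant genes were ENSDARG00000116751, ENSDARG00000112702, zgc:158463, ENSDARG00000116076 and si:dkey-153m14.1, and together they held between 2.71% and 90.5% of the reads of a library. The share was 34.3%, 3.61% and 4.56% in the WT libraries at 0 dpa and 57.9%, 2.71% and 32.3% in the knockout (KO) libraries at 0 dpa. At 1 dpa it was 62.2%, 58.3% and 84.3% in WT and 10.9%, 72.0% and 76.9% in KO. At 4 dpa it lay between 87.5% and 90.5% in WT and between 79.0% and 82.9% in KO. Below, the 4 libraries with a share under 20% are called low-share libraries: WT 0 dpa replicates 2 and 3, KO 0 dpa replicate 2 and KO 1 dpa replicate 1. Reads in all other genes, which set the depth of the comparisons, ranged from 10.5 M to 75.5 M, and at 4 dpa from 10.5 M to 10.9 M in WT against 16.4 M to 19.7 M in KO. Spearman correlations between replicates of a group, across genes, ranged from 0.930 for KO 0 dpa replicates 1 and 2 to 0.991 for WT 1 dpa replicates 1 and 2. All 18 libraries were counted as separate samples because the labels name separate pools. Replicates differed by more than counting error (smallest chi-square over degrees of freedom 36.2), which rules out copies of the same counts and does not test whether pools were shared.

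**Figure D1:**
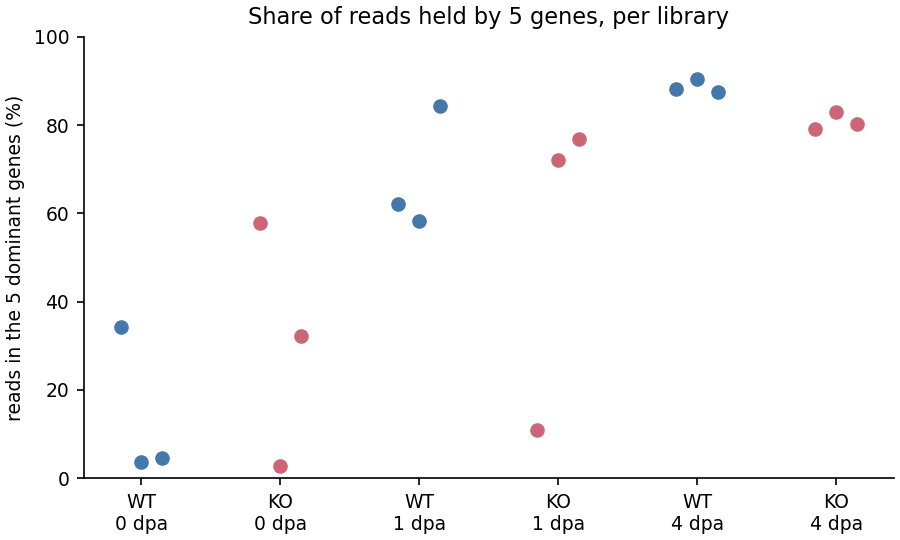
Share of the reads of each library (vertical axis, percent) that fell in the 5 most abundant genes, by genotype and time, with 1 point per library in replicate order. The share spans 2.71% to 90.5%, varies most between replicates at 0 dpa and in KO at 1 dpa, and lies above 79% in every library at 4 dpa.

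The main question of the design was which genes differ between KO and WT fins at each time, and whether genes near each other do so. The deleted element is non-coding, so no gene's value checks the deletion itself, and the labels do not place it in the genome. The gene that set KO apart from WT at every time was tenm1, which encodes a teneurin, a transmembrane adhesion protein best known from neurons. Its mean normalised count rose in KO from 920.4 to 2272 at 0 dpa (2.49-fold), from 435 to 1861 at 1 dpa (4.27-fold) and from 658 to 1845 at 4 dpa (2.82-fold), with 3 libraries per group. At each time, all 3 KO libraries lay above all 3 WT libraries. Averaged over the times, tenm1 was 3.11-fold higher (log2 1.64, SE 0.10, limma adjusted p = 3.49e-07), and it was the 1 gene called at all 3 times.

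Averaged over the 3 times, 32 of 22779 tested genes differed between genotypes, 11 higher and 21 lower in KO. The uncharacterised gene si:ch211-26b3.4 was higher (log2 1.61, SE 0.14, adjusted p = 3.27e-05), as were si:ch211-207c6.6 (log2 1.66, adjusted p = 3.40e-04) and GPR50, a relative of the melatonin receptors (log2 1.23, adjusted p = 9.05e-03). A copy of ACSL4, which activates long-chain fatty acids, and copies of the netrin receptor gene UNC5D and of the endocytic adaptor gene DAB2 were also higher. Among the lower genes were both copies annotated CMKLR1, the receptor of the chemoattractant chemerin (log2 -2.31 and -2.20), isg15, which encodes an interferon-induced ubiquitin-like protein (log2 -2.47, adjusted p = 2.11e-03), casp22, named as a caspase gene (log2 -0.89), PIWIL2, which acts in the silencing of transposons in germ cells (log2 -1.12), a copy of SSH1, a phosphatase that activates cofilin (log2 -0.89), and LAS1L, a ribosome assembly factor (log2 -0.46). Lower genes with clone names included si:dkey-111b14.5, si:dkey-10g2.5, si:ch211-114l13.11, si:dkeyp-91h6.2, si:dkey-47k20.6, si:ch211-170p16.1, si:dkey-267p21.1 and si:dkey-125i10.3, with log2 values from -1.60 to -3.46. Both CMKLR1 copies had similar values in every library, and reads could be shared between them, so which copy differed is uncertain. The values of si:ch211-170p16.1 and si:dkey-267p21.1 were also close in every library, and equal in each KO library at 4 dpa. Reads could be shared there too, so these may not be separate differences. In each WT group and in KO at 0 dpa, si:dkey-10g2.5, si:ch211-114l13.11, si:dkeyp-91h6.2 and si:dkey-47k20.6 ranked the replicates in the same order. In KO at 1 and 4 dpa the order differed among these genes. Their calls may therefore not be separate differences either, and whether they share reads was not tested. The unnamed genes ENSDARG00000116053, ENSDARG00000114691 and ENSDARG00000109867 were higher at low values, with means under 30 in every group. edgeR called 33 genes and DESeq2 56. The call of SAMD10 (log2 -0.52, adjusted p = 0.0417) held in 11 of 30 settings and that of LAS1L in 16 of 30.

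**Figure D2:**
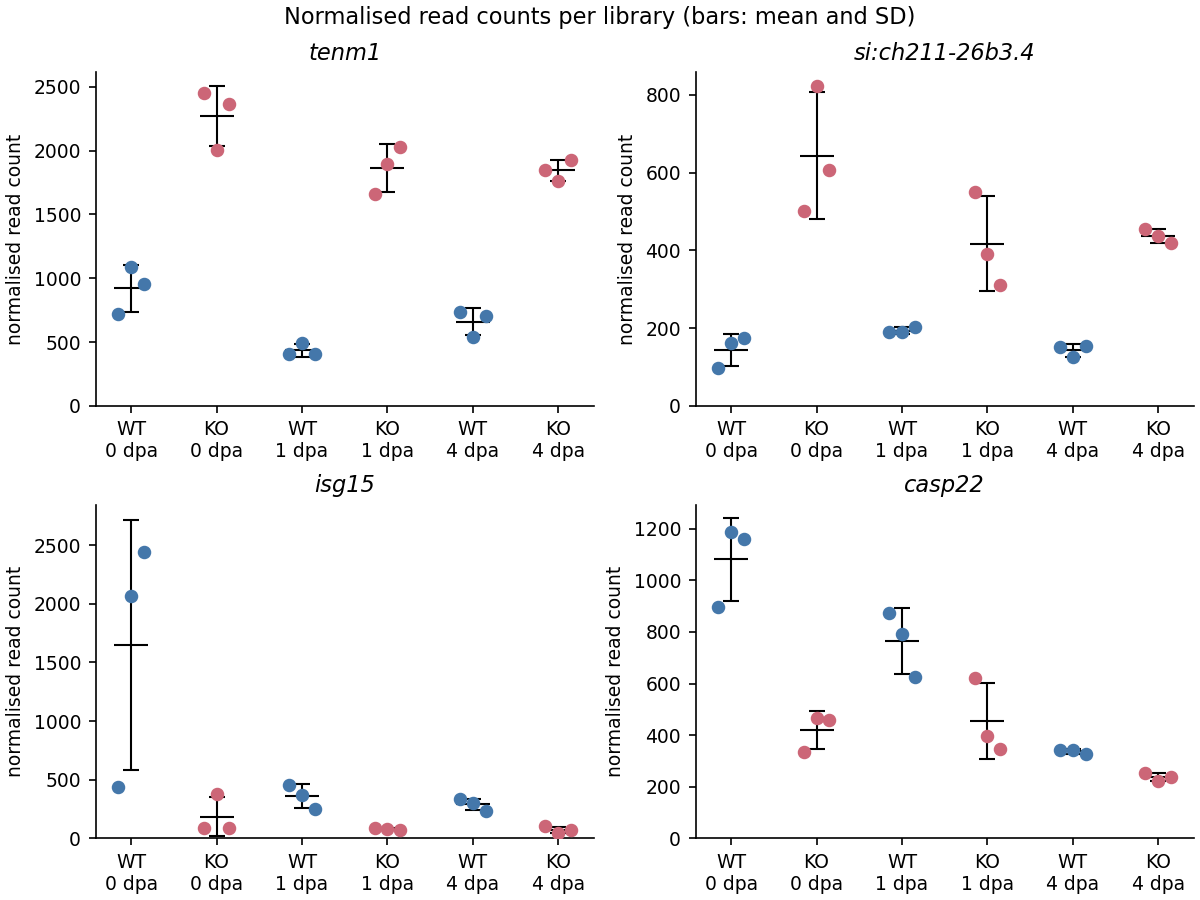
Normalised read counts (vertical axis) of tenm1, si:ch211-26b3.4, isg15 and casp22 in each library, by genotype and time, with the mean as a horizontal line and the SD as an error bar (3 libraries per group). KO libraries lie above WT libraries for tenm1 and si:ch211-26b3.4 at every time, and below them for isg15, where WT at 0 dpa also varies most (mean 1649, SD 1065).

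In uncut fins at 0 dpa, 23 genes differed between genotypes, 8 higher and 15 lower in KO. Besides tenm1, si:ch211-26b3.4 rose 4.48-fold (adjusted p = 0.00272), si:ch211-207c6.6 rose 4.22-fold, and nup54, a component of the nuclear pore, rose 2.41-fold from a mean of 160.1 to 388. The copy of ACSL4 rose 2.60-fold, those of UNC5D (log2 1.07) and DAB2 (log2 1.00) rose as well, and pard6a, a cell polarity gene, rose 1.84-fold. isg15 fell from a mean of 1649 to 183, 9.17-fold (log2 -3.20, SE 0.58, adjusted p = 0.0457). The CMKLR1 copies fell 5.94- and 5.28-fold and PIWIL2 4.16-fold, from a mean of 104.5 to 24.8. casp22 fell 2.58-fold, SSH1 2.35-fold and LAS1L 1.75-fold. CCNE1, which encodes cyclin E, fell 2.11-fold, and NCAPH, a condensin subunit, fell 2.08-fold. isg15 was at 2065 and 2443 in the low-share WT libraries and at 439 in the other WT library, against 376 in the low-share KO library and 88.3 and 84.7 in the other KO libraries, and its call held in 9 of 18 settings. The call of tenm1 at this time held in 16 of 18 and that of si:ch211-26b3.4 in 17, while SSH1 held in 9, ACSL4, pard6a and LAS1L in 10 each and CCNE1 in 11. That of si:ch211-207c6.6 held in 12, with log2 values from 1.27 to 2.52 between settings.

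The 0 dpa calls came from limma-trend over all 22779 tested genes. At an unadjusted p under 0.05 there were 1093 genes, and the groups did not overlap for 7.14% of genes, where chance gives 10%. edgeR called 31 genes, all 23 of these among them, and DESeq2 96; the count was 1 without KO replicate 3, 3 and 4 without WT replicates 3 and 2, 8 without KO replicate 1 and 39 without KO replicate 2. With the 6 libraries of 0 dpa fitted alone no gene was called, and without the low-share libraries 6 were.

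At 1 dpa, the stage of the wound epidermis, the 1 gene called between genotypes was tenm1, 4.27-fold higher in KO (adjusted p = 3.35e-05). On simulated data 8% of 2-fold changes were recovered at this time, so smaller differences could be missed. si:ch211-26b3.4 had means of 194 in WT and 417 in KO, and isg15 means of 360 in WT and 77.0 in KO, but neither passed the test at this time alone. Nor did the copy of ACSL4, 2.84-fold higher in KO (adjusted p = 0.0941). With the share term, added after the data were seen, limma called 10 genes. Among them were isg15 and the copy of ACSL4 (adjusted p = 0.00804 each) and si:ch211-26b3.4 (adjusted p = 0.0442). limma called 1 gene, against 465 at an unadjusted p under 0.05, and the groups did not overlap for 8.45% of genes, where chance gives 10%. edgeR called 1 gene and DESeq2 20. Without KO replicate 1, the low-share library of this time, 3 genes were called.

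At 4 dpa, during blastema outgrowth, 8 genes differed, 5 higher and 3 lower in KO. tenm1 and si:ch211-26b3.4 were again higher, the latter from a mean of 143 to 436 (log2 1.61, adjusted p = 0.0207). HAO1, which encodes a peroxisomal glycolate oxidase, rose from a mean of 6.61 to 44.6 (log2 2.63, SE 0.38, adjusted p = 0.0176). The WT mean of HAO1 lies below the floor of 3 reads per library, 7.42 to 7.47 in these WT libraries, so its fold is uncertain. A copy of SLC25A10, a mitochondrial dicarboxylate carrier gene, and si:ch1073-406l10.3 were at 0 in all 3 WT libraries and at means of 11.7 and 10.8 in KO. Against a floor of 3 reads per library these are at least 1.58- and 1.45-fold higher. Both were named after their values were seen, and their WT libraries had the fewest reads outside the dominant genes. Both CMKLR1 copies (log2 -2.50 and -2.48) and si:dkey-111b14.5 (log2 -2.88) were lower. Calls held in 18 of 18 settings for tenm1, in 14 and 13 of 18 for the CMKLR1 copies, in 13 of 18 for si:ch211-26b3.4 and in 9 of 18 for si:dkey-111b14.5. They held in 13 of 17 for SLC25A10, in 11 of 17 for HAO1 and in 7 of 17 for si:ch1073-406l10.3. At an unadjusted p under 0.05 there were 925 genes, and the groups did not overlap for 10.95% of genes, where chance gives 10%. edgeR called 4 genes and DESeq2 15. The count was 2 without WT replicate 2, 24 and 21 without WT replicates 1 and 3, and 5, 3 and 3 without KO replicates 1, 2 and 3.

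Whether genotype differences lay close together was asked by ordering genes along chromosomes, since the study asks about genes near the silencer. Of the tested genes, 14379 could be placed among their neighbours. At 0 dpa, 10 of the placed genes were called, and tenm1, LAS1L and casp22 fell within 1 window of 20 neighbouring tested genes. Random placement of 10 calls gave a window with as many in few of 10000 permutations (permutation p = 6e-04). For the average over times, the fullest windows also held 3 calls (permutation p = 4e-04, 8 placed calls). Fullest windows were tied: LAS1L, casp22 and si:ch211-26b3.4 also fell within 1 window, without tenm1, at 0 dpa and for the average, as did casp22, si:ch211-26b3.4 and si:dkey-125i10.3 for the average. In the order of tested genes, isg15 lay 18 steps to one side of tenm1, and on the other side LAS1L lay 7, casp22 15, si:ch211-26b3.4 22 and si:dkey-125i10.3 31 steps away. The gene next to tenm1, sh2d1aa, had a log2 value of 1.19 averaged over the times and was not called. At 4 dpa no window held more than 1 call (permutation p = 1, as any placement gives at that count), and at 1 dpa tenm1 was the 1 call. However, 2 of the 3 placed calls at 4 dpa lay on the chromosome of tenm1. These were tenm1 and si:ch211-26b3.4, whose distance of 22 steps is too wide for a window of 20 genes. Without WT replicate 2 or 3, or KO replicate 1 or 3, the fullest window at 0 dpa held 1 call.

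**Figure D3:**
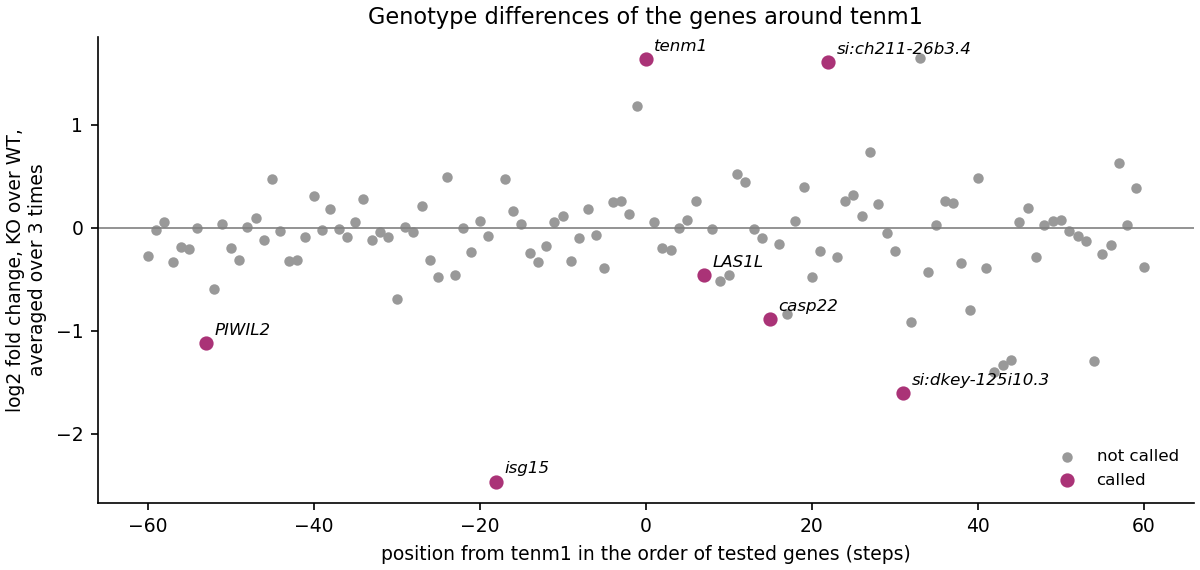
Log2 fold change of KO over WT, averaged over the 3 times (vertical axis), for tested genes within 60 steps of tenm1 in gene order (horizontal axis, steps). Called genes are larger and named: tenm1 and si:ch211-26b3.4 are higher in KO, and isg15, LAS1L, casp22, PIWIL2 and si:dkey-125i10.3 are lower, between many genes near 0.

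Between genotypes, gene groups fixed in advance differed by small amounts, and isg15 was the 1 member of any group to be called by itself. At 0 dpa, 4 of 34 lists were called by camera. Cell cycle genes were lower in KO (median log2 -0.31, 40 measured, 1 called when adjusted over the list alone, adjusted p = 3.46e-07), as were AP-1 and immediate early genes, which respond within minutes to a stimulus (median log2 -0.29, 2 of 19 adjusted over the list alone, adjusted p = 0.0116), and fibroblast markers (median log2 -0.26, 0 of 23 adjusted over the list alone, adjusted p = 0.018). Circadian clock genes were higher (median log2 0.18, 0 of 40 adjusted over the list alone, adjusted p = 0.0116). For all 4 the adjusted p was 0.757 with an estimated correlation. Of the 6 libraries at 0 dpa, 2 WT and 1 KO were low-share libraries.

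At 1 dpa 10 lists were called. The KO fins had higher values of inflammatory cytokines and STAT3 targets (median log2 0.48, adjusted p = 4.85e-04), antigen presentation genes (0.39, 0.00136), the interferon response (0.36, 0.00538), neutrophil markers (0.34, 0.0172), superficial epidermis markers (0.37, 0.0172), mitochondrially encoded genes (0.28, 0.0172) and cell cycle genes (0.30, 2.88e-05). Bone matrix and osteoblast genes were lower (median log2 -0.18, adjusted p = 0.00445). For these 8 lists the adjusted p was 0.481 with an estimated correlation. Endothelium and lymphatic markers (median log2 -0.26, adjusted p = 0.00136) and retinoic acid pathway genes (median log2 -0.13, adjusted p = 0.00432) were lower, each with an adjusted p = 0.0835 with an estimated correlation. No member of these 10 lists passed the test over all genes, and 1 interferon gene did so adjusted over the list alone. The interferon gene isg15 was lower in KO at this time (log2 -2.18, SE 0.58), against the direction of its list. KO replicate 1 was the low-share library of this time. At 4 dpa, 3 lists were called: AP-1 genes were lower (median log2 -0.44, adjusted p = 0.00301), and bone matrix genes (0.22, 0.00379) and cell cycle genes (0.14, 0.0207) were higher, with 0 members called adjusted over the list alone. Their adjusted p was 0.49, 0.49 and 0.612 with an estimated correlation. Without WT replicate 1, no list was called at 4 dpa, and without WT replicate 2 or 3, 2 were called at 0 dpa.

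Whether the response to amputation differed between genotypes was asked with interaction terms. limma called 0 genes for the change from 0 to 1 dpa and 0 for the change from 0 to 4 dpa, against 950 and 888 genes at an unadjusted p under 0.05. edgeR called 0 and 0 genes and DESeq2 5 and 1. On simulated data the test recovered 42% of genes with a 4-fold interaction at 1 dpa and 48% at 4 dpa, and 2% at each with a 2-fold interaction.

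The response of WT fins at 1 dpa gives the background against which the genotypes are set. Among the genes that rose most, ntrnl2 rose from a mean of 143 to 16960.0 (log2 6.97), jac4 90.2-fold, teni.1 83.2-fold and f5, which encodes coagulation factor V, 61.2-fold, from a mean of 17.2 to 1090.0. A copy of FN1, which encodes the provisional matrix protein fibronectin, rose 57.3-fold (log2 5.84, SE 0.32, adjusted p = 4.24e-09), EDNRB 41.0-fold and PDLIM3 54.3-fold. Among the genes that fell, PCK1, the rate-limiting enzyme of gluconeogenesis, went from a mean of 893 to 22.7 (log2 -5.37, adjusted p = 2.32e-06), the G protein regulator RGS2 from 2610.0 to 58.4, and the chemokine gene ccl19b from 2373 to 82.3. In all, 9154 genes changed, 4341 higher and 4813 lower, among 11217 at an unadjusted p under 0.05. Without WT 0 dpa replicate 2, 5956 genes were called, and for WT 1 vs 0 dpa, genes called with only libraries with a high share of dominant genes were 5400.0.

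By group, 29 of 40 cell cycle genes rose and 0 fell (30 adjusted over the list alone, adjusted p = 1.74e-13, or adjusted p = 0.0952 with an estimated correlation), with the mitotic kinase gene plk1 28.5-fold and CENPF 15.5-fold higher. Of the wound and blastema signalling factors, 17 of 25 rose and 3 fell (20 adjusted over the list alone, adjusted p = 5.33e-07, or adjusted p = 0.0775 with an estimated correlation), among them the cytokine genes il11a, 18.7-fold, and il11b, 26.9-fold, and a copy of the activin gene INHBA, 14.8-fold. Matrix remodelling enzymes (11 of 22 rose and 4 fell, 16 adjusted over the list alone, adjusted p = 0.00233, or adjusted p = 0.0596 with an estimated correlation) were led by adam8a, 32.5-fold, and the collagenase gene mmp13a, 22.3-fold. Wound and blastema matrix genes (13 of 22 rose and 6 fell, 19 adjusted over the list alone, adjusted p = 0.00375, or adjusted p = 0.185 with an estimated correlation) included vcana, a versican gene, 34.8-fold, and a copy of the tenascin gene TNC, 28.0-fold. Antigen presentation genes fell in 12 of 17 and rose in 0 (12 adjusted over the list alone, adjusted p = 2.49e-04, or adjusted p = 0.279 with an estimated correlation), as for mhc2dab (log2 -3.66), cd74a (log2 -2.81) and b2m (log2 -2.49). AP-1 and immediate early genes fell in 11 of 19 and rose in 3 (15 adjusted over the list alone, adjusted p = 0.00319, or adjusted p = 0.349 with an estimated correlation), with FOSB at log2 -3.70 and JUN at log2 -2.63. Bone matrix and osteoblast genes fell in 11 of 19 and rose in 3 (14 adjusted over the list alone, adjusted p = 0.0495, or adjusted p = 0.393 with an estimated correlation), with ENTPD5 at log2 -3.92, IFITM5 at log2 -3.62 and a copy of COL10A1 at log2 -3.13. The other 27 lists were not called at this time. Signs of the median, the mean and the test differed for basal epidermis (0.08, -0.26, up), macrophages (0.03, -0.21, up), fin ray joint and actinotrichia (-0.05, -0.08, up) and melanocytes (-0.13, -0.02, up). Without WT 0 dpa replicate 2, 12 lists were called.

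At 4 dpa in WT fins, and1 and and2, which encode the actinodins of the actinotrichia (the fibrils at the edge of a growing fin), rose 283-fold and 328-fold, and1 from a mean of 794 to 221500.0. Of genes in the secretory calcium-binding phosphoprotein family, enam rose 242-fold, scpp7 137-fold, scpp5 123-fold and ambn 61.0-fold. plxnd1, a semaphorin receptor gene, rose 89.6-fold and the copy of TNC 57.7-fold (log2 5.85, SE 0.23, adjusted p = 1.30e-10). cldn29 and msrb2 were at 0 in all 3 WT libraries at 4 dpa, from means of 84.5 and 71.6 at 0 dpa, and so at least 11.4- and 9.62-fold lower. In all, 12657 genes changed, 5911 higher and 6746 lower. The share of the dominant genes was 87.5% to 90.5% in these WT libraries at 4 dpa, against 3.61% to 34.3% at 0 dpa. Changes with time and with that share are therefore largely confounded here. With a term for the share, added after the data were seen, 10575 genes were called, 9699 of them also called without it.

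Of the 34 lists, 13 were called at 4 dpa in WT, and 3 of them held with an estimated correlation. These were matrix remodelling enzymes (18 of 22 rose and 3 fell, 21 adjusted over the list alone, adjusted p = 1.73e-05, and adjusted p = 0.00724 with an estimated correlation), such as mmp11b, 11.2-fold higher, wound and blastema matrix genes (15 of 22 rose and 3 fell, 18 adjusted over the list alone, adjusted p = 6.10e-06, and adjusted p = 0.0343 with an estimated correlation), and endothelium and lymphatic markers (13 of 19 rose and 1 fell, 14 adjusted over the list alone, adjusted p = 6.10e-05, and adjusted p = 0.0295 with an estimated correlation), among them the apelin receptor gene aplnrb, 7.27-fold, and the VEGF receptor gene KDR, 5.38-fold. Cell cycle genes (26 of 40 rose and 0 fell, 27 adjusted over the list alone) were called at adjusted p = 1.18e-07, and had adjusted p = 0.119 with an estimated correlation. Signalling factors (16 of 25 rose and 2 fell, 18 adjusted over the list alone, adjusted p = 6.10e-05, or adjusted p = 0.0929 with an estimated correlation) included WNT5A, 15.6-fold higher. Hedgehog and BMP pathway genes (13 of 26 rose and 3 fell, 16 adjusted over the list alone, adjusted p = 0.0113, or adjusted p = 0.0676 with an estimated correlation) were called as well. Wnt targets and inhibitors (12 of 24 rose and 5 fell, 18 adjusted over the list alone, adjusted p = 0.0462, or adjusted p = 0.0932 with an estimated correlation) included LEF1, 6.51-fold higher. Fin ray joint and actinotrichia genes (4 of 7 rose, adjusted p = 0.00227, or adjusted p = 0.0676 with an estimated correlation) and osteoclast genes (4 of 10 rose, adjusted p = 0.0444, or adjusted p = 0.101 with an estimated correlation) had 4 calls each adjusted over the list alone, and the osteoclast gene ocstamp rose 13.5-fold.

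Downward, AP-1 and immediate early genes fell in 14 of 19 and rose in 0 (15 adjusted over the list alone, adjusted p = 3.87e-06, or adjusted p = 0.0929 with an estimated correlation), with ier2b at log2 -4.24 and FOSL1 at log2 -3.48. Inflammatory cytokines and STAT3 targets fell in 19 of 26 and rose in 2 (22 adjusted over the list alone, adjusted p = 2.66e-04, or adjusted p = 0.425 with an estimated correlation), with cxcl8b.1 at log2 -4.41 and a copy of SOCS3 at log2 -4.15. Antigen presentation genes fell in 12 of 17 and rose in 2 (14 adjusted over the list alone, adjusted p = 0.00139, or adjusted p = 0.311 with an estimated correlation). Superficial epidermis markers fell in 12 of 18 and rose in 0 (12 adjusted over the list alone, adjusted p = 0.00227, or adjusted p = 0.425 with an estimated correlation), with icn2 at log2 -4.07 and AGR2 at log2 -3.60. The other 21 lists were not called at 4 dpa. Calls higher and lower were 9 and 2 of 19 for bone matrix, 3 and 7 of 16 for basal epidermis, 3 and 3 of 16 for mucous cells and ionocytes, 4 and 7 of 17 for macrophages, 5 and 7 of 16 for neutrophils, 1 and 5 of 13 for lymphocytes and 4 and 7 of 21 for the interferon response. They were 3 and 7 of 15 for melanocytes, 4 and 6 of 18 for iridophores and xanthophores, 3 and 9 of 20 for nerve and Schwann cells, 3 and 1 of 12 for erythrocytes, 4 and 1 of 21 for skeletal muscle, 8 and 5 of 18 for FGF targets, 6 and 6 of 25 for the retinoic acid pathway and 5 and 4 of 18 for the Notch pathway. They were 5 and 11 of 28 for heat shock and the unfolded protein response, 9 and 14 of 40 for the circadian clock, 5 and 13 of 29 for sterol and lipid metabolism, 1 and 2 of 13 for oestrogen-responsive and sex-biased genes and 3 and 6 of 13 for mitochondrially encoded genes. For fibroblasts, with 11 higher and 8 lower of 23, the median and mean log2 values (-0.05 and -0.19) and the direction of the test (up) differed in sign. The same held for skeletal muscle (-0.09, 0.03, up), mucous cells and ionocytes (0.15, -0.13, up), the retinoic acid pathway (0.07, -0.12, up) and the Notch pathway (0.07, -0.05, up).

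In KO fins at 1 dpa, ntrnl2 rose 128-fold, jac4 103-fold, f5 80.1-fold and plk1 34.3-fold, and PCK1 (log2 -5.22), RGS2 (log2 -5.14) and the immediate early gene csrnp1a (log2 -5.52) fell. At 4 dpa and2 rose 361-fold, enam 338-fold, scpp5 311-fold and and1 277-fold. limma called 6680 genes at 1 dpa (3505 higher and 3175 lower) and 11160 at 4 dpa (5299 higher and 5861 lower). Of these, 2713 were higher and 2500 lower in both genotypes at 1 dpa, where independent calls would share 668 and 671, and 0 went opposite ways. At 4 dpa 4522 were higher and 5149 lower in both, where independent calls would share 1380 and 1740, and 2 went opposite ways. Across genes, which are not independent replicates, the fold changes of the genotypes had a Pearson correlation of 0.858 at 1 dpa and 0.915 at 4 dpa, and the genotypes shared no libraries. In KO, camera called 12 lists at 1 dpa, 3 of them with an estimated correlation, and 16 at 4 dpa, 7 of them with an estimated correlation. In KO at 1 dpa, 37 of 40 cell cycle genes rose and 0 fell (adjusted p = 4.4e-25, and adjusted p = 0.0267 with an estimated correlation). For KO 1 vs 0 dpa, genes called were 3405 with only the libraries of the groups compared, and 10140 with a term for the share of dominant genes. For KO 4 vs 0 dpa they were 11864 with that term, 10782 of them also called without it. The share also rose with time in KO, from 2.71% to 57.9% at 0 dpa to 79.0% to 82.9% at 4 dpa.

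**Figure D4:**
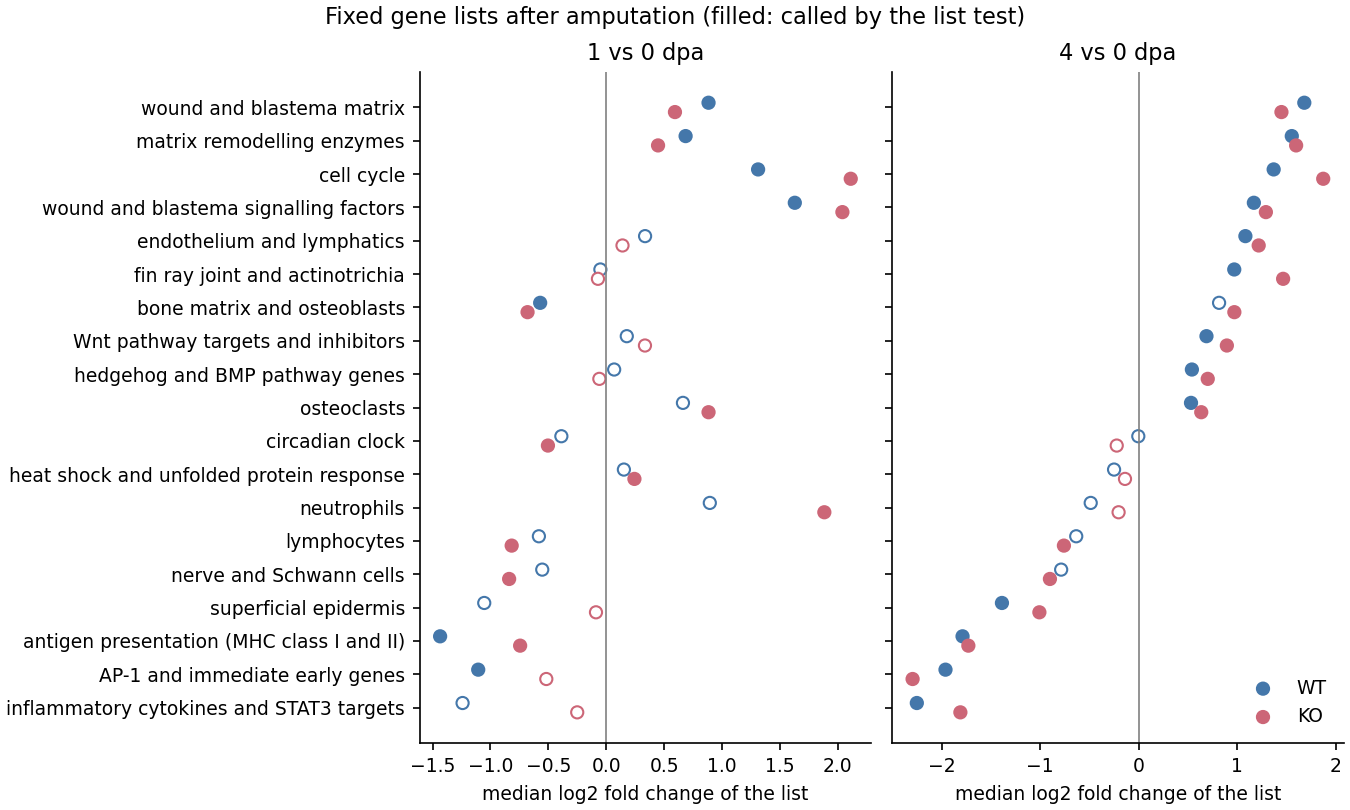
Median log2 fold change (horizontal axes) of the fixed gene lists that were called in at least 1 of the 4 comparisons over time, at 1 dpa (left) and 4 dpa (right) against 0 dpa, in WT and KO. Filled points were called by camera with its preset correlation, and the medians of WT and KO have the same sign for most lists, as for cell cycle genes (1.31 and 2.11 at 1 dpa).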

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

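The tests of placement and distance on the chromosome, the term for the share of dominant genes and the list tests of the interactions were chosen only after the result was seen. The bound for the ratio of responses was set before that ratio was computed.

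Genes called between genotypes gathered on the chromosome that carries tenm1: averaged over the times, 7 of 8 placed calls lay there, although it holds 5.88% of the placed tested genes. Of the 32 genes called for the average, only 8 could be placed, so the pattern covers a minority of the calls. The Fisher test against chance placement gave p = 1.79e-08. It cannot exclude chance by itself, since the chromosome was chosen for tenm1, which is 1 of the 7 calls. The window permutation for the average ran over all chromosomes and did not rest on that choice (permutation p = 4e-04). Variants carried along on the chromosome that holds the deletion could account for the pattern. Genes 21 to 100 steps from tenm1 passed an unadjusted p under 0.01 more often than genes of other chromosomes (9.38% against 0.539%, Fisher p = 8.08e-14). Within 20 steps, tenm1 left out, 15% passed, and over 100 steps away 2.17%. The Fisher test is not separate support, since genes 21 to 100 steps away include PIWIL2, si:ch211-26b3.4 and si:dkey-125i10.3, which are among the 7 calls. It also counts neighbours such as gbgt1l3 and gbgt1l6 as independent. Release of neighbouring genes from the silencer would raise them, so by itself it cannot account for the 5 genes that were lower in KO. Other or indirect effects of s1 on these 5 genes were not tested. For the 2 higher genes, tenm1 and si:ch211-26b3.4, release stays open beside carried variants, because the labels do not place s1.

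Gene lists differed between genotypes at each time, 4 at 0 dpa, 10 at 1 dpa and 3 at 4 dpa. The uneven share of the dominant genes could account for part of this: with a term for that share, 1 of 4 lists kept its call and direction at 0 dpa (cell cycle) and 4 of 10 at 1 dpa (bone matrix, cell cycle, endothelium and the retinoic acid pathway). At 4 dpa no library is a low-share library, so the term leaves the fold changes of that time as they are and acts on the tests through the spread alone, and the difference in share there (79.0% to 82.9% in KO, 87.5% to 90.5% in WT) is not corrected. Members that move together between libraries may also produce such calls, as 0 lists held with an estimated correlation.

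Fewer genes were called 1 vs 0 dpa in KO than in WT fins, 6680 against 9154. The uneven share of the dominant genes could contribute. With a term for that share, the count was 10140 in KO against 7116 in WT. These counts cannot settle it, because the low-share libraries are placed unevenly over genotypes and times. Across 9671 genes, chosen as called 4 vs 0 dpa in both genotypes in the same direction, the median KO over the median WT log2 change was 0.684 without the term and 1.165 with it (1.06 to 1.341 with 1 library left out). The ratio with the term met the bound set against a smaller response in KO fins, but that bound was wrong to rest on the term alone: the low-share WT libraries are all at 0 dpa, while KO has 1 at 0 dpa and 1 at 1 dpa, so the term moved the WT median from 1.05 to 0.62 and left the KO median at 0.72. A smaller response in KO fins therefore stays open.

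The following lists differed in the interaction of genotype with 1 vs 0 dpa, and none held with an estimated correlation. The AP-1 list had a median log2 interaction of 0.49 (adjusted p = 0.00316, or 0.556 with an estimated correlation). Inflammatory cytokines and STAT3 targets had 0.61 (0.0129, or 0.698). The interferon response had 0.50 (0.00262, or 0.556). Antigen presentation had 0.49 (0.0129, or 0.63). The cell cycle had 0.63 (1.03e-09, or 0.344). Endothelium and lymphatics had -0.26 (0.028, or 0.344). Heat shock and the unfolded protein response had 0.31 (0.0265, or 0.698). Mitochondrially encoded genes had 0.53 (0.0129, or 0.698). With the share term and the preset correlation, the interferon response (adjusted p = 0.0423) and the cell cycle (1.43e-08) passed, and AP-1 (0.0587), inflammatory cytokines (0.889), antigen presentation (0.549), endothelium (0.0841), heat shock (0.685) and mitochondrially encoded genes (0.634) did not.

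In the interaction of genotype with 4 vs 0 dpa, bone matrix and osteoblasts had a median log2 interaction of 0.48 (adjusted p = 4.61e-04, or 0.263 with an estimated correlation). The interferon response had 0.28 (0.0329, or 0.664). The cell cycle had 0.56 (3.49e-09, or 0.263). Fibroblasts had 0.34 (0.00223, or 0.329). With the share term and the preset correlation, the interferon response did not pass (adjusted p = 0.0715), and bone matrix (1.23e-04), the cell cycle (8.49e-09) and fibroblasts (0.00505) did.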

How the results depend on the processing

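The term for the share of dominant genes and the fits to libraries with a high share of them were chosen only after the result was seen, and all other settings were planned.

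For KO vs WT at 0 dpa, the 23 genes called became 96 with DESeq2, 15 with a replicate block, 0 with only the libraries of the groups compared, 37 with the share term and 6 with high-share libraries only. With 1 library left out the count ran from 1 without KO_0dpa replicate 3 to 39 without KO_0dpa replicate 2, with 4 without WT_0dpa replicate 2, 3 without WT_0dpa replicate 3 and 8 without KO_0dpa replicate 1. At 1 dpa, the 1 gene became 3 with pseudocount 8, 20 with DESeq2, 10 with the share term and 5 with high-share libraries only, and ran from 1 to 3, the latter without KO_1dpa replicate 1.

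For KO vs WT at 4 dpa, the 8 genes became 14 with pseudocount 0.25, 5 with pseudocount 8, 20 with no filter on low values, 4 with minimum value 50, 4 with edgeR, 15 with DESeq2, 4 with only the libraries of the groups compared and 17 with the share term. The count ran from 2 without WT_4dpa replicate 2 to 24 without WT_4dpa replicate 1, with 21 without WT_4dpa replicate 3, 5 without KO_4dpa replicate 1, 3 without KO_4dpa replicate 2 and 3 without KO_4dpa replicate 3. Averaged over the 3 times, the 32 genes became 56 with DESeq2 and 64 with the share term, and ran from 28 to 37 with 1 library left out.

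For the interaction of genotype with 1 vs 0 dpa, the 0 genes called by limma (950 at an unadjusted p under 0.05, 0 by edgeR) became 5 with DESeq2, 1 with the share term and 1 with high-share libraries only, and stayed at 0 with any library left out. For 4 vs 0 dpa, the 0 genes called by limma (888 at an unadjusted p under 0.05, 0 by edgeR) became 1 with DESeq2 and 1 with high-share libraries only, and ran from 0 to 1, the latter without KO_0dpa replicate 2.

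For WT 1 vs 0 dpa, genes called became 5400 with only libraries with a high share of dominant genes, and ran from 5956 without WT_0dpa replicate 2 to 10968 without WT_0dpa replicate 1. For KO 1 vs 0 dpa, genes called became 3405 with only the libraries of the groups compared and 10140 with the term for the share of dominant genes, and ran from 4765 to 7446. At 4 vs 0 dpa they ran from 10336 to 13593 in WT and from 8936 to 11455 in KO.

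Fixed lists called for KO vs WT at 0 dpa became 0 with an estimated correlation, 1 with the share term and 2 with high-share libraries only, and ran from 2 without WT_0dpa replicate 2 or WT_0dpa replicate 3 to 6. At 1 dpa they became 0 with an estimated correlation and ran from 8 to 13. At 4 dpa they became 0 with an estimated correlation and 5 with high-share libraries only, and ran from 0 without WT_4dpa replicate 1 to 4. For WT 1 vs 0 dpa they became 0 with an estimated correlation, 12 with the share term and 13 with high-share libraries only, and ran from 6 to 12, the latter without WT_0dpa replicate 2. For WT 4 vs 0 dpa they became 3 with an estimated correlation and ran from 11 to 14.

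The most called genes in a window at 0 dpa ran from 1, without WT_0dpa replicate 2, WT_0dpa replicate 3, KO_0dpa replicate 1 or KO_0dpa replicate 3, to 4. At 1 dpa the 1 gene became 2 at an unadjusted p under 0.001 and 2 with the share term, and at 4 dpa 2 in a window of 40 genes, 2 at an unadjusted p under 0.001 and 3 with the share term. Both stayed at 1 with any library left out.

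Over 164 named-gene results, 1888 settings left the call the same and 72 made it weaker. With 1 library left out these were 1182 and 114, and 0 turned direction. Genes were named because they were called, so no setting could strengthen a call. The totals pool changes over time with genotype differences, and the weakened settings fell mostly on the genotype differences. At 0 dpa between genotypes, for example, the call of isg15 held in 9 of 18 settings. Replicates of the same number were not treated as pairs: correlations of their deviations at 0 dpa were 0.735, 0.603 and -0.219, at 1 dpa 0.199, -0.234 and 0.281, and at 4 dpa 0.007, 0.031 and 0.019.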

Other observations

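The tests with a term for the share of dominant genes were chosen only after the result was seen, and the splits of libraries were planned.

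Averaged over the 3 times, AP-1 and immediate early genes were lower in KO (adjusted p = 0.0138, or 0.718 with an estimated correlation), and erythrocyte genes (median log2 0.30, adjusted p = 0.0138, or 0.705) and circadian clock genes (adjusted p = 0.0233, or 0.936) were higher. Across all 22779 tested genes, genotype effects at 0 dpa had a Pearson correlation of -0.163 (Spearman -0.329) with those at 1 dpa and of 0.074 (Spearman 0.041) with those at 4 dpa. Low-share libraries were mostly WT at 0 dpa and KO alone at 1 dpa, and their part in the negative value was not tested. Among the 23 genes selected by their call at 0 dpa, 20 had the same sign at 1 dpa and 21 at 4 dpa.

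For KO vs WT at each time there are 10 splits of the 6 libraries, which are too few. At 0 dpa, 2 of 10 splits gave as many genes (23 real, highest other 9528, with the low-share libraries on one side). At 1 dpa 1 of 10 did (1 real, highest other 0) and at 4 dpa 1 of 10 (8 real, highest other 0). For fixed lists, 4 of 10 did at 0 dpa (4 real, highest other 6), 1 of 10 at 1 dpa (10 real, highest other 8) and 1 of 10 at 4 dpa (3 real, highest other 2). For the most called genes in a window, 2 of 10 did at 0 dpa (3 real, highest other 18), 1 of 10 at 1 dpa (1 real, highest other 0) and 1 of 10 at 4 dpa (1 real, highest other 0).

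Over time there are also 10 splits, too few. For WT 1 vs 0 dpa 1 of 10 gave as many genes (9154 real, highest other 0), for WT 4 vs 0 dpa 1 of 10 (12657 real, highest other 1), for KO 1 vs 0 dpa 1 of 10 (6680 real, highest other 2256) and for KO 4 vs 0 dpa 1 of 10 (11160 real, highest other 0). For fixed lists it was 4 of 10 for WT 1 vs 0 dpa (7 real, highest other 7) and 2 of 10 for WT 4 vs 0 dpa (13 real, highest other 16).

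For the average and the interactions, 100 splits were used, the real one and others drawn at random. Averaged over the times, 12 of 100 splits gave as many genes as the 32 called, with 7627 as the highest other, so regrouping the libraries could give such a count. The 11 other splits all put the low-share libraries of 0 dpa on one side, and the side of the low-share library of 1 dpa was not examined. With a term for the share of dominant genes, 1 of 100 splits, the real one, gave as many as 64, and the highest other gave 36. At single times with this term, 2 of 10 splits gave as many at 0 dpa (37 real, highest other 264). At 1 dpa it was 1 of 10 (10 real, highest other 5) and at 4 dpa 1 of 10 (17 real, highest other 2). For the interactions, 100 of 100 splits gave at least the 0 genes called for 1 vs 0 dpa (highest other 8872), and 100 of 100 for 4 vs 0 dpa (highest other 5902). Every split reaches a count of 0 whatever the data, so the interaction splits test nothing.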
